A study of Mus musculus with 6 samples.

How the data were processed

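RNA from brown adipose tissue was sequenced by the authors in 6 libraries, 3 from control mice with floxed Bscl2 (Ctrl) and 3 from mice that also carried Ucp1-Cre (BKO). Per the labels, RNA was extracted with Trizol and libraries were made with a TruSeq RNA kit. Per the submitters' processing notes, the tools were CASAVA 1.8, TopHat2 2.0.12 and Cufflinks 2.2.1 with the genome build NCBIM37, and their options and annotation are not given in the sources used here. The deposited values are FPKM per gene, normalized by the authors for transcript length and library size. They are not counts, so no count model was used and the depth of each library is unknown.

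Columns were assigned to samples by the sample names in the labels' descriptions. Those names call the control libraries MT and the BKO libraries WT. The assignment followed the descriptions, and the level of Bscl2 checked it. Replicate numbers came from the sample titles.

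The table lists 12966 gene symbols, with 0 duplicates. No value in BKO-3 lies between 0 and 0.486 FPKM, whereas the other libraries hold between 439 and 743 values below that level. The listing therefore looks filtered on BKO-3, and a gene that dropped below that level there would not be listed. This can hide genes that were lower in BKO. A total of 9 mitochondrial genes are listed at 0 in every library, so a 0 can be a failed estimate and is described only as listed at 0. The sum of FPKM ranged from 1119228 to 1617963 in 5 libraries and was 2808874 in BKO-3.

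Values were transformed as log2(FPKM + 1), and 11397 genes with a mean of at least 1 FPKM over the 6 libraries were tested. Fold changes on this scale understate the change of genes with low values, and folds in the text are ratios of mean FPKM. Linear models were fitted with limma 3.58.1 in R 4.3.3, with an intensity trend in the empirical Bayes step, no covariate and Benjamini-Hochberg adjustment at 0.05. An exact two-sided permutation test was added for Bscl2, and with 3 against 3 libraries its p cannot go below 0.1.

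Before the data were examined, 34 gene lists were fixed for the tissue, its other cell types and the deleted gene, and 32 had the 5 tested members that a test needed. Lymphocyte markers (1 tested) and neutrophil and mast cell markers (2 tested) were too few and were left out. Lists were tested with camera at a preset correlation of 0.01 and the same trend, adjusted over lists, with an estimated correlation and fry as alternatives.

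The rule for named genes was also fixed then. It took Bscl2, the largest changes past the threshold in either direction, up to 4 passing members of each list described, or the 2 most abundant members where fewer than 2 passed, and a set of genes given whatever their test. Because fewer genes passed than the rule allowed for, all 19 were named. Members were named by this rule for the called lists, except for a gene that is not reported here. Sdf2l1, Manf, Trib3 and Lgals3 were chosen after their values were seen.

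Gene lengths were taken from GENCODE vM21 by symbol, as the union of exons, for 98.1% of tested genes. That annotation is on another build than the authors used, so no coordinates are printed. The names AL732525.2 and AL845466.1 are given as they stand in the table.

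The steps were tested on simulated data for the BKO against Ctrl comparison with 11397 genes. Of these, 200 were changed by known folds, and the circadian clock list was also raised. The test recovered 74% of 2-fold and 97% of 4-fold changes, with 182 calls of which 9 were false. The simulated noise was independent between genes, and no library was made to stand apart. These rates therefore need not hold for the real libraries.

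Alternatives fixed beforehand were other pseudocounts, filters, scalings and empirical Bayes settings, library weights, a replicate block, a muscle score as covariate, other thresholds and leaving out each library. Restricting the test to genes of at least 1000 nt and leaving Bscl2 out of its list were added after seeing the data.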

Results

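Gene expression was measured by RNA sequencing in brown adipose tissue of 10 week old male C57BL/6J mice. The tissue came from control animals carrying floxed Bscl2 (Ctrl, 3 libraries) and from animals that also carried a Ucp1 promoter-driven Cre recombinase (BKO, 3 libraries). Bscl2 encodes seipin, an endoplasmic reticulum protein that acts in lipid droplet formation, and Ucp1-Cre is active in brown adipocytes. The table held 12966 genes as FPKM, the number of fragments scaled by transcript length and library size, of which 11397 had a mean of at least 1 FPKM over the 6 libraries and were tested. The number of reads per library is unknown, because the values are not counts. The labels do not state that each library came from a separate animal, so p-values measure only the spread between these samples, which may be technical.

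The comparison of BKO with Ctrl asks how the tissue's transcripts differ when Bscl2 is lost in brown adipocytes. Only BKO mice carried the Cre, so an effect of the transgene itself cannot be told apart from loss of Bscl2. The targeted gene was measured first, as a check of the labels. Bscl2 stood at 109 ± 6.05 FPKM in Ctrl (SD, n = 3) and at 17.4 ± 1.32 FPKM in BKO (SD, n = 3), which is 16.0% of the Ctrl level. It fell by 2.57 on the log2(FPKM + 1) scale (SE 0.0788, limma with Benjamini-Hochberg adjusted p = 3.95e-05). All 3 BKO libraries lay below all 3 Ctrl libraries, and the exact two-sided permutation p was 0.1, the smallest that 3 against 3 libraries allow.

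Apart from Bscl2, the genes that passed the test all rose in BKO, and several of them are known from macrophages. Lyz2, the lysozyme of macrophages, rose from 23.8 ± 6.20 to 84.2 ± 10.5 FPKM (SD, n = 3 per group). Mmp12, macrophage elastase, rose from 0.164 ± 0.0768 to 4.92 ± 0.583 FPKM. Plin2, a protein that coats lipid droplets, rose 1.70-fold from 292 ± 13.9 to 496 ± 30.9 FPKM. Ifi27l2a, an interferon-inducible gene, rose 3.16-fold from 235 ± 24.3 to 743 ± 114 FPKM. In all, 18 genes were higher and 1 was lower at an adjusted p below 0.05 (limma, Benjamini-Hochberg) over the 11397 tested. The groups did not overlap in 1032 higher and 777 lower genes, 15.9% of those tested, where chance gives 10%. At an unadjusted p below 0.05 there were 756 higher and 401 lower genes, against 740 and 500 with median ratio rescaling and 634 and 623 with quantile normalization. Dividing the libraries as Ctrl-1, BKO-1 and BKO-2 against the rest gave 1031 such genes, against 1157 for the real groups. These counts alone therefore cannot show an effect of the genotype.

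**Figure D1:**
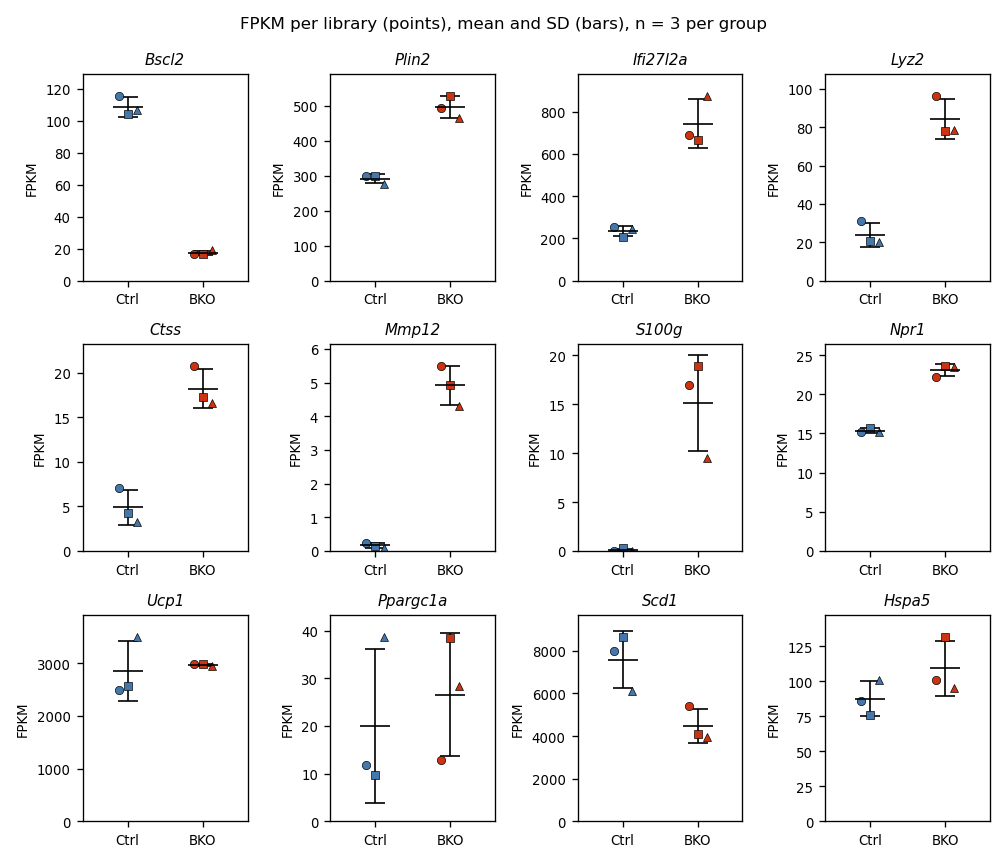
FPKM (vertical axes, starting at 0) of 12 genes in each Ctrl (blue) and BKO (red) library, with circles, squares and triangles for replicates 1, 2 and 3, and the mean and SD of each group as black bars. Bscl2 lay between 104 and 116 FPKM in Ctrl and between 16.5 and 18.9 FPKM in BKO, while the Ppargc1a values of the groups overlapped.

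The other genes that rose spanned several functions. Ctss, a lysosomal protease of antigen-presenting cells, rose 3.74-fold to 18.2 ± 2.18 FPKM. Tyrobp, a signalling adaptor of myeloid cells, rose 2.37-fold to 13.4 ± 1.38 FPKM. Gpnmb, a glycoprotein of lipid-laden macrophages, rose from 0.255 ± 0.123 to 2.24 ± 0.530 FPKM, Ms4a7 from 0.573 ± 0.277 to 2.66 ± 0.402 FPKM, and Slc11a1, a metal transporter of phagosomes, from 1.117 ± 0.142 to 3.24 ± 0.491 FPKM. Phgdh, the entry enzyme of serine synthesis, rose 2.53-fold, and the natriuretic peptide receptor gene Npr1 rose 1.504-fold from 15.4 ± 0.288 to 23.1 ± 0.738 FPKM. Dpep1 rose 1.73-fold, Slc9a3r1 2.03-fold, Tesc 2.58-fold and the histone gene Hist1h4h 1.91-fold. S100g, a calcium-binding protein, was listed at 0 in Ctrl-1 and Ctrl-3 and at 0.261 FPKM in Ctrl-2, against 15.1 ± 4.93 FPKM in BKO. AL732525.2 and AL845466.1 were listed at 0 in all 3 Ctrl libraries, and at 13.5 ± 4.39 and 93.5 ± 51.8 FPKM in BKO. A value listed at 0 can be a failed estimate, so absence in Ctrl is not shown. Lyz2, Hist1h4h and Ifi27l2a belong to families of similar genes, so their reads could have been split between copies.

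Many single-gene calls were lost with 5 libraries, while the log2 changes moved little. Npr1 changed by 0.56 and by 0.54 to 0.58 with 1 library left out, and did not pass in any of those fits, and Ctss by 1.76 and 1.56 to 2.01. There were 5 higher genes without BKO-1, 8 without Ctrl-2, 11 without Ctrl-3, 11 without BKO-2 and 30 without BKO-3, and between 1 and 3 lower genes when any 1 library was left out. Calls were also lost with all 6 libraries. Of the 19, 13 remained with quantile normalization and 9 with the muscle score as covariate. Bscl2, Ifi27l2a, Mmp12, S100g, AL732525.2 and AL845466.1 passed the test in each alternative in which they were tested.

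Markers of macrophages were higher in BKO as a group. Of 22 tested members, 4 rose over all genes tested (Lyz2, Gpnmb, Tyrobp and Ms4a7), 18 did not pass, and 16 were higher when adjusted over the list alone. The median log2 change was 0.91 and camera called the list with an adjusted p = 5.13e-20, while the adjusted p = 0.386 with an estimated correlation. Emr1, the gene of the F4/80 antigen, stood at 1.101 ± 0.300 FPKM in Ctrl and 2.25 ± 0.214 FPKM in BKO (limma with Benjamini-Hochberg adjusted p = 0.198). Lgals3, named after its values were seen, stood at 3.34 ± 1.72 and 25.01 ± 11.8 FPKM.

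Markers of the other cell types of the tissue showed smaller medians. The endothelial list had a median log2 change of -0.01 over 19 genes, with a mean of 0.01 (camera adjusted p = 0.907). The smooth muscle and pericyte list had a median of 0.09 (adjusted p = 0.212), the sympathetic nerve and Schwann cell list -0.00 with a mean of 0.02 (adjusted p = 0.894) and the erythroid list -0.14 (adjusted p = 0.271). The preadipocyte and fibroblast list was called higher with a median of 0.14 (adjusted p = 0.0197), and the adjusted p = 0.477 with an estimated correlation. None of its 15 members passed over all genes tested, and 1 was higher when adjusted over the list alone. Its median was 0.245 without Ctrl-1 and 0.09 without Ctrl-3. Gsn stood at 165 ± 32.1 and 213 ± 23.5 FPKM and Ly6c1 at 126 ± 10.7 and 131 ± 20.1 FPKM in Ctrl and BKO. Skeletal muscle markers did not separate the groups (median 0.00, adjusted p = 0.699), but their mean log2 level ranged from 3.02 in Ctrl-2 to 5.24 in Ctrl-1. Camera called them higher without Ctrl-1 (adjusted p = 0.00116) and lower without Ctrl-2 (0.00584) or BKO-2 (0.0342), and the erythroid list lower without Ctrl-3 (0.000299).

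**Figure D2:**
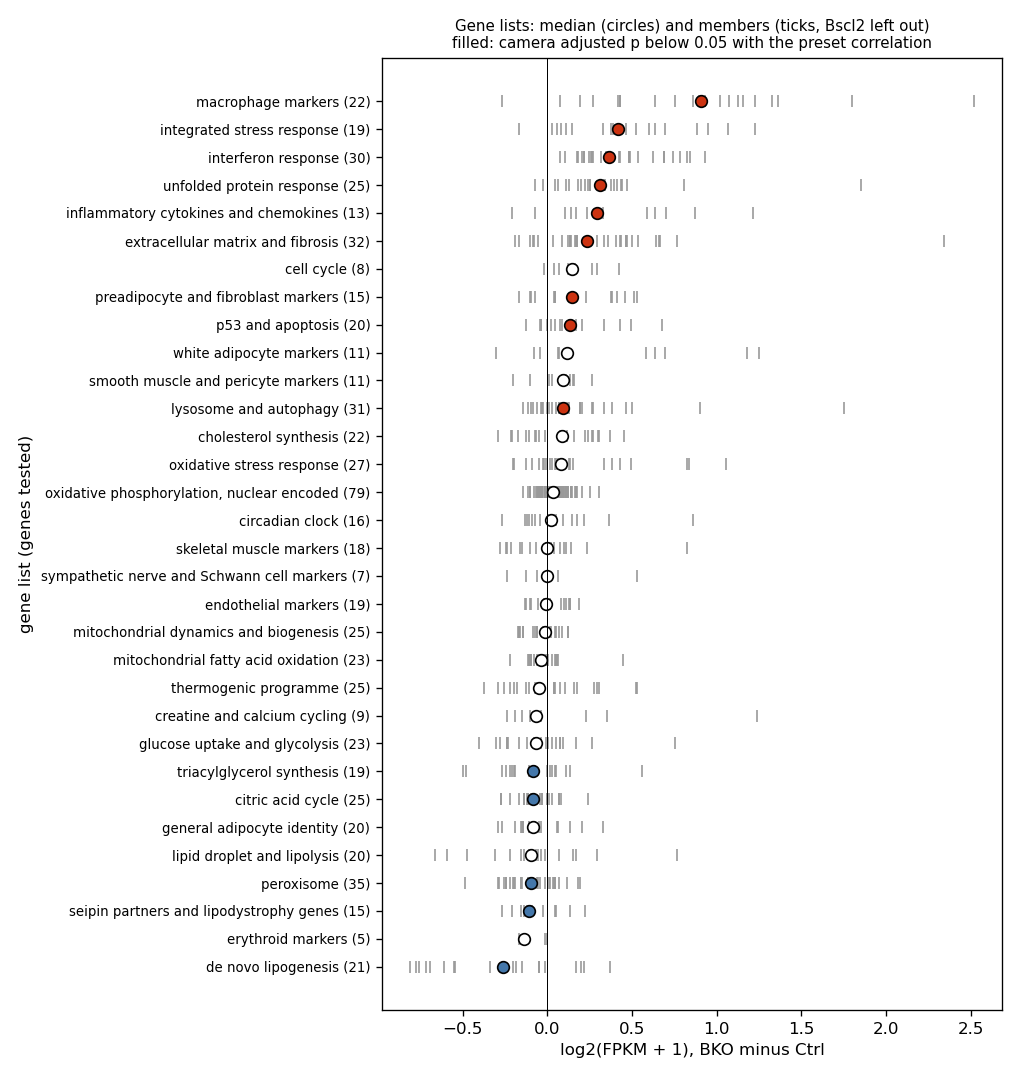
Log2(FPKM + 1) of BKO minus Ctrl (horizontal axis) for the 32 gene lists tested. Ticks are members, circles are medians and brackets give the number of genes tested. Bscl2 has no tick but counts in the median and the number of its list. Filled circles, red for higher and blue for lower, mark the 14 lists with a camera adjusted p below 0.05 at the preset correlation, led by the macrophage list at a median of 0.91.

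The lists of the unfolded protein response and of the integrated stress response were called higher. None of the 25 members of the unfolded protein response list passed over all genes tested, 14 were higher when adjusted over the list alone, and the median log2 change was 0.31. Camera gave an adjusted p = 5.07e-11, and the adjusted p = 0.386 with an estimated correlation. The chaperone gene Hspa5 stood at 87.5 ± 12.5 and 109 ± 19.6 FPKM in Ctrl and BKO, and Calr at 74.3 ± 5.91 and 102 ± 13.7 FPKM. Sdf2l1 and Manf, named after their values were seen, stood at 0.951 ± 0.225 and 6.64 ± 3.48 FPKM and at 17.9 ± 2.01 and 33.1 ± 9.80 FPKM. In the integrated stress response list 1 of 19 members rose (Phgdh), 5 were higher when adjusted over the list alone, and the median was 0.42 (camera adjusted p = 4.7e-07, and adjusted p = 0.386 with an estimated correlation). Its most abundant members were Cebpb, at 213 ± 34.0 and 267 ± 22.5 FPKM, and Atf4, at 72.4 ± 8.51 and 78.4 ± 11.7 FPKM. Trib3, named after its values were seen, stood at 2.399 ± 0.476 and 7.35 ± 3.06 FPKM, and Fgf21 was not analysed here.

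Interferon and matrix genes were also called higher. Whether these lists, and those of cytokines and lysosomes below, rose apart from the macrophage markers was not tested. All 30 members of the interferon response list had a positive log2 change, none passed over all genes tested, and 5 were higher when adjusted over the list alone (median 0.36, camera adjusted p = 3.43e-11, and adjusted p = 0.403 with an estimated correlation). Without Ctrl-1 the median was 0.58, the mean log2 level of the list being 3.785 in Ctrl-1, 3.40 in Ctrl-2 and 3.22 in Ctrl-3 against 3.80 in BKO-3, the lowest of the BKO libraries. B2m and H2-K1, genes of antigen presentation, stood at 604 ± 130 and 801 ± 25.8 FPKM and at 171 ± 51.7 and 223 ± 15.1 FPKM. Of 32 extracellular matrix and fibrosis genes, 1 rose (Mmp12, a protease that degrades matrix) and 3 were higher when adjusted over the list alone (median 0.23, camera adjusted p = 2.9e-07, and adjusted p = 0.403 with an estimated correlation). Col1a1, type I collagen, stood at 9.51 ± 2.02 and 13.7 ± 3.89 FPKM, Dcn at 69.1 ± 11.3 and 84.2 ± 6.30 FPKM and Sparc at 269 ± 29.5 and 285 ± 14.3 FPKM. None of 13 cytokine and chemokine genes passed over all genes tested, 4 were higher when adjusted over the list alone, and the median was 0.29 (camera adjusted p = 0.000226, and adjusted p = 0.403 with an estimated correlation). Cxcl12 stood at 28.0 ± 2.03 and 31.7 ± 1.36 FPKM and Cxcl9 at 10.9 ± 4.16 and 9.03 ± 1.81 FPKM. In the lysosome and autophagy list 1 of 31 members rose (Ctss), 3 were higher when adjusted over the list alone, and the median was 0.09 (camera adjusted p = 0.00125, and adjusted p = 0.403 with an estimated correlation). Ctsd stood at 477 ± 23.0 and 446 ± 30.9 FPKM and Psap at 517 ± 30.4 and 520 ± 12.7 FPKM. The p53 and apoptosis list had a median of 0.13, and none of its 20 members passed over all genes or when adjusted over the list alone (camera adjusted p = 0.0233, and adjusted p = 0.539 with an estimated correlation). Its median was 0.08 without Ctrl-2 and without BKO-2. Ccng1 stood at 52.97 ± 2.14 and 55.7 ± 0.970 FPKM and Phlda3 at 92.2 ± 20.5 and 89.6 ± 19.5 FPKM.

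Genes of fatty acid synthesis were called lower as a list, although the mean log2 level of the list overlapped between the groups. That level was 7.035, 7.031 and 6.779 in Ctrl-1, Ctrl-2 and Ctrl-3, and 6.973, 6.659 and 6.352 in BKO-1, BKO-2 and BKO-3. None of 21 de novo lipogenesis genes passed over all genes tested, 4 were lower when adjusted over the list alone, and the median log2 change was -0.26 (camera adjusted p = 0.00053, and adjusted p = 0.588 with an estimated correlation). Scd1, stearoyl-CoA desaturase, stood at 7583 ± 1327 FPKM in Ctrl and 4486 ± 796 FPKM in BKO, and Fasn, fatty acid synthase, at 1924 ± 231 and 1432 ± 669 FPKM. Without BKO-3 the median of this list was -0.12 and it was no longer called (adjusted p = 0.0796), and the log2 change of Fasn went from -0.55 to -0.11. Without BKO-1 the median was -0.40 and the log2 change of Fasn -0.87. The peroxisome list had a median of -0.10 over 35 genes (camera adjusted p = 0.000579, and adjusted p = 0.403 with an estimated correlation), and none of its members passed over all genes or when adjusted over the list alone. Ech1 stood at 778 ± 30.3 and 803 ± 33.2 FPKM and Scp2 at 469 ± 3.41 and 508 ± 18.9 FPKM, both against the direction of their list. The citric acid cycle list had a median of -0.08 over 25 genes (camera adjusted p = 0.0159, and adjusted p = 0.561 with an estimated correlation), with 0 members past the test over all genes or adjusted over the list alone by limma, and a median of -0.05 without BKO-3, where it was not called (adjusted p = 0.239). Sdha stood at 818 ± 6.11 and 793 ± 19.0 FPKM. Triacylglycerol synthesis had a median of -0.08 over 19 genes (camera adjusted p = 0.0233, and adjusted p = 0.386 with an estimated correlation), again with 0 members past the test by limma over all genes or adjusted over the list alone. Its median was -0.13 without Ctrl-1 and without Ctrl-2. Pck1 stood at 1769 ± 57.5 and 1547 ± 164 FPKM and Gpd1 at 1790 ± 69.7 and 1697 ± 207 FPKM. The list of seipin partners and lipodystrophy genes was called lower (median -0.11, camera adjusted p = 0.00379, and adjusted p = 0.403 with an estimated correlation), Bscl2 being the single member of 15 that fell over all genes and when adjusted over the list alone. With Bscl2 left out, an alternative chosen after seeing the data, the median was -0.0995 and the list was not called (camera adjusted p = 0.0621). Without Ctrl-1 the median with Bscl2 was -0.05, and the list was still called (adjusted p = 0.0162). Agpat2 stood at 592 ± 25.4 and 497 ± 85.2 FPKM and Cidec at 498 ± 23.4 and 469 ± 49.5 FPKM.

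The thermogenic programme was not called. Its 25 tested members had a median log2 change of -0.05 and a mean of 0.02 (camera adjusted p = 0.804). Ucp1, the uncoupling protein of brown fat, stood at 2851 ± 562 FPKM in Ctrl and 2966 ± 19.7 FPKM in BKO (difference 0.07 on the log2 scale, 95% interval -0.26 to 0.41, limma). Ppargc1a, a coactivator of mitochondrial biogenesis, stood at 20.0 ± 16.2 and 26.5 ± 12.9 FPKM, a difference smaller than the spread within either group. Nuclear-encoded oxidative phosphorylation had a median of 0.03 over 79 genes (adjusted p = 0.271), mitochondrial fatty acid oxidation -0.04 over 23 genes (adjusted p = 0.212) and mitochondrial dynamics and biogenesis -0.01 over 25 genes (adjusted p = 0.116). Camera called the mitochondrial dynamics list lower without Ctrl-1 (adjusted p = 0.0351), Ctrl-2 (0.0488) or BKO-2 (0.0443), with adjusted p of up to 0.703 among its alternatives. It called oxidative phosphorylation lower without BKO-2 (0.0296) and higher without BKO-3 (0.00123). Cpt1b, the carnitine palmitoyltransferase of muscle and brown fat, stood at 364 ± 8.36 and 341 ± 27.2 FPKM.

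The general adipocyte identity and lipid droplet lists lay just above the threshold, and some alternatives called them lower. The general adipocyte list had a median log2 change of -0.09 over 20 genes (camera adjusted p = 0.055), and was called in 2 of 17 alternatives at the preset correlation (adjusted p 0.0308 to 0.151), 1 of them without BKO-3 (0.0308). Adipoq stood at 625 ± 41.5 and 570 ± 97.5 FPKM and Pparg, the nuclear receptor that directs adipocyte differentiation, at 102 ± 13.7 and 113 ± 16.8 FPKM. In the lipid droplet and lipolysis list Plin2 rose, while 19 of 20 members did not pass, and 1 was higher and 1 lower when adjusted over the list alone (median -0.09, adjusted p = 0.055). This list was called in 5 of 17 alternatives (adjusted p 0.0342 to 0.191), among them without BKO-2 (0.0342) and without BKO-3 (0.0486). Pnpla2, adipose triglyceride lipase, stood at 1539 ± 67.5 and 1379 ± 53.7 FPKM (limma with Benjamini-Hochberg adjusted p = 0.569). White adipocyte markers had a median of 0.11 and a mean of 0.38 over 11 genes (adjusted p = 0.055), with 0 members past the test over all genes by limma, and 4 higher and 1 lower when adjusted over the list alone. This list was called in 10 of 17 alternatives (adjusted p 0.00654 to 0.351, medians 0.02 to 0.58), among them without Ctrl-1, Ctrl-2, BKO-2 or BKO-3, and its adjusted p = 0.477 with an estimated correlation. Cell cycle genes had a median of 0.14 (adjusted p = 0.055) and were called higher in 6 of 16 alternatives (adjusted p 0.00407 to 0.191), among them without BKO-2 (0.0177). Among the remaining lists, oxidative stress response had a median of 0.08 (adjusted p = 0.0746), glucose uptake and glycolysis -0.07 (adjusted p = 0.176), cholesterol synthesis 0.09 (adjusted p = 0.546), creatine and calcium cycling -0.07 with a mean of 0.12 (adjusted p = 0.673) and the circadian clock 0.02 with a test direction of lower (adjusted p = 0.875). Of these, oxidative stress response was called higher in 2 of 17 alternatives (adjusted p 0.00963 to 0.425), 1 of them without BKO-3 (0.00963), cholesterol synthesis higher without BKO-3 (0.0038), and glucose uptake lower without BKO-1 (0.0378) or BKO-2 (0.0292).

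In all, camera called 14 of 32 lists with its preset correlation of 0.01, 9 higher and 5 lower. With an estimated correlation it called 0, at a lowest adjusted p of 0.386. Fry, whose directional p tests whether the genes of a list move on balance one way, called 0 at a lowest adjusted p of 0.0672, and its mixed p, which tests for change in either direction, called 10. Neither fry test compares a list with other genes. The list calls therefore rest on the preset correlation of 0.01. Among the 14 called lists the estimated correlation ran from -0.000657 for triacylglycerol synthesis to 0.704 for de novo lipogenesis. It was 0.377 for macrophage markers and 0.606 for the interferon response. Each of the other 9 ways to divide the 6 libraries into 3 and 3 also called lists, between 3 and 15 of them. Leaving out 1 library ended the call of de novo lipogenesis (BKO-3), the citric acid cycle (Ctrl-2, Ctrl-3 or BKO-3, with an adjusted p of up to 0.239), triacylglycerol synthesis (Ctrl-3, 0.17), preadipocyte and fibroblast markers (Ctrl-2, Ctrl-3 or BKO-1, up to 0.0968) and p53 and apoptosis (Ctrl-3, BKO-1 or BKO-2). The p53 and apoptosis call also ended at a mean of at least 5 FPKM (adjusted p = 0.0875). Mean log2 levels of the called lists per library overlapped between the groups for de novo lipogenesis, cytokines and chemokines, and the peroxisome. They also overlapped for the citric acid cycle, preadipocyte and fibroblast markers, p53 and apoptosis, and triacylglycerol synthesis.

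The libraries were similar, with 1 standing apart. Pearson correlations across genes of log2(FPKM + 1) ranged from 0.966 to 0.978 between libraries other than BKO-3, and from 0.948 to 0.960 between BKO-3 and the others. Mitochondrial transfer RNA genes made up 74.4% of the FPKM sum in BKO-3 and between 45.1% and 64.5% in the other libraries. All but 10 genes had a value of at least 0.486 FPKM in BKO-3, where the other libraries listed between 90 and 111 genes at 0.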

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

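The tests below on cell share, lymphoid tissue, scaling and low values were chosen after the results were seen, as was the split of short genes from genes of unknown length. The tests of library correlations among genes of at least 1000 nt and of the listing minimum were chosen before their results were seen, unlike the separate restriction of the gene tests to such genes.

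Among genes below the mean FPKM filter, which did not enter the main tests, 5 macrophage markers had all BKO libraries above all Ctrl libraries. They were Itgam, Itgax, Trem2, Atp6v0d2 and Clec7a. Trem2 stood at 0.178 ± 0.178 and 1.58 ± 0.236 FPKM in Ctrl and BKO (SD, n = 3), and Atp6v0d2 at 0.0241 ± 0.00785 and 1.01 ± 0.367 FPKM. Cd163, a marker of resident macrophages, went the other way, from 1.04 ± 0.232 to 0.468 ± 0.124 FPKM. Of all 1569 genes below the filter, 235 were separated higher and 44 lower in the same sense, where chance separates 10% of genes in 3 against 3 libraries, or 5% in each direction. The listing minimum in BKO-3 favours genes that are higher there.

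The higher level of macrophage markers in BKO was set against a lower share of adipocytes, which would raise the markers of every other cell type alike. The endothelial list had a median log2 change of -0.0109 with an upper quartile of 0.102, below the macrophage lower quartile of 0.428, which argues against that as the whole cause. Lymphoid tissue in BKO-3 was tested by leaving that library out, and the macrophage median was then 1.02 against 0.906 with it. More macrophages in BKO, or more expression in each, both stay open and cannot be separated in whole tissue. Loss of Bscl2 cannot be told apart from the Cre transgene as the source.

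Of the called genes 18 were higher and 1 was lower. The listing minimum may hide lower genes, but with the same minimum applied to each Ctrl library in turn at least 12 of the 18 higher genes stayed listed, so it does not account for all of the imbalance. Scaling did not account for it either, since the share of higher calls was at least 92.3% under both other scalings. Among genes at an unadjusted p below 0.05 the share of higher genes was 65.3%, but 59.7% with median ratio rescaling and 50.4% with quantile normalization, so whether that wider imbalance comes from scaling cannot be told apart from a real one, the scalings giving different answers.

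BKO-3 stood apart from the other libraries. Of 24 listed immunoglobulin genes 23 were highest there (median 1.03 FPKM, against 0 to 0.241 in the others), but nearly all listed genes had a value above the minimum in BKO-3 and it was highest for 28.1% of the 1569 genes below the filter, so these values do not decide whether lymphoid tissue was present. Low values did not account for it, since at a mean of at least 5 FPKM its highest correlation with another library was 0.935, below the lowest of the other pairs, 0.948. Among genes of at least 1000 nt its correlations were 0.986 to 0.988, inside the range of the other pairs (0.981 to 0.990), but that also left out 222 genes of unknown length. With only the 687 genes under 1000 nt left out, its highest correlation was 0.974, still below the lowest of the other pairs, 0.976. Among those 687 genes alone its correlations were 0.842 to 0.886, against 0.893 to 0.952 for the other pairs. Among the 222 genes of unknown length alone they were 0.516 to 0.688, against 0.788 to 0.881. The distance of BKO-3 therefore lay in the short genes and the genes of unknown length. Whether gene length accounts for the distance stays open, because the length of the latter is unknown, and no biological explanation was tested.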

How the results depend on the processing

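The alternative limited to genes of at least 1000 nt and the list without Bscl2 were chosen after seeing the data. The log2 change of Bscl2 stayed past the threshold in each alternative, between -2.635 and -2.530. The 18 higher genes became 9 at a mean of at least 5 FPKM, where fewer genes were tested, 32 with robust empirical Bayes, 48 with arrayWeights, 8 with the muscle score as covariate, 33 at an adjusted p of 0.1 and 11 with a log2 change of at least 1. Leaving out 1 library gave 5 to 30 higher genes: 8 without Ctrl-2, 11 without Ctrl-3, 5 without BKO-1, 11 without BKO-2 and 30 without BKO-3. Of the 19 calls, 6 remained without BKO-1, BKO-2 or Ctrl-2, and all 19 kept their sign there. The 1 lower gene became 6 with arrayWeights, and 1 to 3 when 1 library was left out (3 without Ctrl-1, 2 without Ctrl-3, BKO-2 or BKO-3). Among genes of at least 1000 nt, 23 were higher and 1 lower. Only 13 of the 19 calls were among those genes, and all 13 passed there. The remaining calls were not tested in that alternative. Otherwise the cause was not tested.

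The 14 lists called became 0 with an estimated correlation and 0 by fry's directional p, and 11 to 20 when 1 library was left out. The replicate block gave 23 higher and 2 lower genes and 16 lists. The numbers gave no clear sign of pairing: correlations of deviations were 0.196, -0.104 and -0.100 for replicates 1, 2 and 3. The libraries of replicate 1 correlated best with their own number, and those of replicates 2 and 3 did not. With so few libraries this cannot exclude pairing.

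With only 10 splits of the 6 libraries, the share cannot go below 0.1. The real split called 19 genes and the highest other split 4, so 1 split called as many. For lists the real split called 14 and the highest other 15, and 2 splits called as many. That other split set Ctrl-1, BKO-1 and BKO-2 against the rest.

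Every change of direction concerned a gene or list that had not passed in the report. Leaving out 1 library gave log2 changes of -0.00361 to 0.201 for Atf4, -0.416 to 0.0561 for Cxcl9, -0.140 to 0.0214 for Gpd1, -0.0337 to 0.176 for Ly6c1, -0.238 to 0.149 for Phlda3, -0.0239 to 0.0561 for Psap and -0.0156 to 0.231 for Ucp1. Psap was -0.0426 with quantile normalization and -0.00471 with median ratio rescaling. List medians with 1 library left out ran from 0.00603 to 0.184 for cholesterol synthesis, -0.0645 to 0.0323 for the circadian clock, -0.0708 to 0.458 for creatine and calcium cycling, -0.0559 to 0.0572 for endothelial markers, -0.276 to -0.00337 for erythroid markers, -0.0810 to 0.00587 for glucose uptake and glycolysis, -0.0334 to 0.0654 for oxidative phosphorylation, -0.534 to 0.615 for skeletal muscle, -0.0782 to 0.0782 for nerve and Schwann cells and -0.0423 to 0.0615 for the thermogenic programme. Some of these lists were called by camera with 1 library left out: oxidative phosphorylation lower without BKO-2 (adjusted p = 0.0296) and higher without BKO-3 (0.00123), skeletal muscle higher without Ctrl-1 (0.00116) and lower without Ctrl-2 (0.00584) or BKO-2 (0.0342), cholesterol synthesis higher without BKO-3 (0.0038), erythroid markers lower without Ctrl-3 (0.000299) and glucose uptake lower without BKO-1 (0.0378) or BKO-2 (0.0292). Test directions also turned for the circadian clock (median -0.00184 with quantile normalization, 0.0351 with arrayWeights, 0.0205 with the replicate block and by fry), creatine and calcium cycling (-0.0708 with the muscle score), endothelial markers (-0.00654 at a mean of at least 5 FPKM, -0.0222 with quantile normalization, -0.0109 by fry), skeletal muscle (-0.0351 with quantile normalization, 0.359 with arrayWeights), nerve and Schwann cells (-0.00222 by fry) and the thermogenic programme (-0.052 by fry).

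Over all lists and all named genes except Bscl2, 1328 values stayed on the same side, 136 lost and 42 gained the threshold, and 41 changed direction. The 41 are the changes of direction treated above. The planned sum over duplicate symbols was void, with 0 duplicates, and the planned count-based test was not run because the values are not counts.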

Other observations

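The lists of macrophage genes below and their test were chosen after the results were seen. A hypothesis is that the macrophage genes higher in BKO belong to a lipid-associated state more than to resident macrophages. Of 14 genes of each list, 13 lipid-associated and 11 resident genes were listed, 7 of the former also being in the macrophage list of the report and 2 being called genes. The median log2 change was 0.42 for the lipid-associated and 0.11 for the resident genes. The score difference between the lists was 0.880, 0.924 and 0.793 in Ctrl-1, Ctrl-2 and Ctrl-3 and 1.64, 1.66 and 1.45 in BKO-1, BKO-2 and BKO-3. The mean difference was 0.717 higher in BKO (exact two-sided permutation p = 0.1, the smallest that 3 against 3 allow), and the lists were chosen after the results were seen, so the hypothesis may or may not hold.

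Genes past the threshold without BKO-3 included Sdf2l1 and Manf of the unfolded protein response, Trib3 of the integrated stress response and Lgals3. Their log2 changes there were 2.29, 1.07, 1.58 and 2.99 (limma with Benjamini-Hochberg adjusted p = 0.00969, 0.0364, 0.0285 and 0.037). Of the alternatives that kept each gene in the test, Sdf2l1 passed in 2 of 16 (adjusted p 0.00969 to 0.488), Manf in 1 of 17 (0.0364 to 0.754), Trib3 in 1 of 16 (0.0285 to 0.635) and Lgals3 in 3 of 17 (0.0262 to 0.458). Of these alternatives, Manf and Trib3 passed only where BKO-3 was left out.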
